A study of Mus musculus with 2 samples.

How the data were processed

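Long-read RNA-seq was analysed from tissue labelled as a layer of hippocampus of male B6CASTF1/J mice, the first-generation cross of the C57BL/6 and CAST/Ei backgrounds, at 18 to 20 months of age. The labels give 2 biological replicates, made from 2 µg of RNA each, which form 1 group. Their biosamples differ, but both labels carry 1 shared donor record, and nothing in the labels beyond the biosamples and the replicate numbers says that the samples came from separate animals. A difference between the libraries may therefore be technical. The exact tests between libraries set it against counting error alone, and the tests over exons or molecules describe these libraries. With 1 group there was no comparison between conditions, and no test across replicated groups was possible.

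For each library the authors deposited a table of raw read counts per transcript model, with no normalization, and an annotation of the same models. Per the file headers, each model carries a gene, a TALON class, and the number of exons and the length in nucleotides of the model, not of the reads. Per the labels and the notes deposited with the files, the models were built against mm10 with GENCODE M21 from a filtered alignment of each library, and the libraries were not pooled. The aligner and the versions of the authors' tools are not given in the sources used here. The tables hold models with at least 1 read. All 40761 annotated models with reads, counted in each library separately, had the same exons in GENCODE M21. The labels name SIRV and ERCC spike-ins. The SIRV measurement planned before the data were examined was not analysed here. ERCC transcripts, chosen after the data had been seen, were used instead, but they are not taken as a measure of wrongly called splicing, which was not measured.

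Replicate 1 held 649547 reads and replicate 2 held 1089843, of which 643367 and 1079179 came from endogenous genes. ERCC reads were left out of library totals. CPM values were computed from the deposited counts by scaling to the total of endogenous reads of each library. A single read was worth 1.55 CPM in replicate 1 and 0.927 CPM in replicate 2, and the 3-count floor used for folds against 0 was 4.66 and 2.78 CPM per library. Unannotated antisense and intergenic models were merged over the libraries by overlap on the same strand, because identifiers of unannotated models are made separately in each library. Multi-exon models were matched between libraries by chromosome, strand and intron chain.

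TALON classes are named here as follows. Known models have an annotated intron chain, ISM models hold part of one (incomplete splice match), NIC models combine annotated splice sites in a chain that is not annotated, and NNC models have at least 1 splice site that is not annotated. Genomic models overlap a gene without matching its splicing, antisense models lie opposite an annotated gene, and intergenic models lie outside annotated genes.

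Reads per gene were compared between the libraries with an exact two-sided binomial test against replicate 1's share of endogenous reads, over genes with 10 or more reads in total, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a CPM ratio of 2 or more. Such tests on reads compare these libraries, not conditions. The biological coefficient of variation was estimated with edgeR 4.0.16 in R 4.3.3, with an intercept and no test. Gene lists were fixed before the data were examined, and the median log2 CPM ratio of members with 10 or more reads was placed among 10000 random lists of the same size matched on mean expression. The lists were 16 sets of cell type markers, 11 gene groups, a sex check and a list of genes with known alternative splicing in brain. Class shares were compared with Fisher's exact test. Isoform use was measured over known, NIC and NNC models of at least 2 exons in genes with 50 or more such reads in each library, with an isoform counted as in use at 10% or more in each library. Percent spliced in was computed for internal exons with 20 or more informative reads in each library, with 10% to 90% called intermediate, over 95% called constitutive, and exons of 27 nt or shorter called microexons. Leading isoform shares, and the inclusion of exons intermediate in both libraries, were compared between libraries with Fisher's exact test. All intervals are 95% Clopper-Pearson intervals, all tests are two-sided, and intervals and floors cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used, with DESeq2 1.42.0 for alternative size factors.

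The binomial test was tested on simulated data drawn from the real means and totals, with 13055 genes tested. The simulation held counting error alone (Poisson), not the further spread between these libraries, so its counts do not cover that spread. There the test called 8 of 50 genes changed 2-fold, 37 of 50 changed 4-fold, 43 of 50 changed 8-fold and 44 of 50 changed 16-fold, and 5 unchanged genes.

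The rule for named genes, also set before the data were examined, took the 10 genes with the highest mean CPM, the 4 detected members of each list with the highest mean CPM and its called members, the 10 called genes with the largest ratio in each direction among those with 20 or more reads, the leading isoforms of at most 30 genes of the splicing list with 20 or more full-chain reads in each library, its intermediate exons with the 10 others of most reads, and the 10 NIC or NNC chains and 5 intergenic loci with most reads in both libraries. From these sets examples are given, and any other gene is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here. Levels of the Y-linked genes and Xist are given only as a check of the labels. The alternatives were TMM and DESeq2 scaling, other read minimums and ratios, single transcript classes, multi-exon models only, thinned reads, stricter matching of chain ends, other isoform and inclusion thresholds, and each replicate left out.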

Results

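The data were long reads of RNA from hippocampal layer tissue of aged male B6CASTF1/J mice, with 2 libraries forming a single group. The 643367 endogenous reads of replicate 1 and 1079179 of replicate 2 were assigned to models with mean lengths of 2894 and 2942 nt, weighted by reads. With ERCC models included, the libraries held 112266 and 146701 transcript models. In the check of sex-linked genes, 5 of 6 were detected and 0 of 2 libraries did not match the sex on the labels. With no contrast between conditions, the measurements address which genes and isoforms the tissue expressed, and where the libraries differed by more than counting error.

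Abundant annotated genes included neuronal and metabolic ones. Ncdn, a neurite outgrowth gene, stood at 4858 ± 159 CPM (SD, n = 2). Apoe, the astrocytic lipid carrier, followed at 4012 ± 560 CPM, then Ubb at 3716 ± 19.3 and Cpe, a neuropeptide-processing enzyme, at 3393 ± 266 CPM (SD, n = 2). The glycolytic Aldoa stood at 2627 ± 113 CPM, Calm2 at 2600 ± 81.1 and the ferritin heavy chain gene Fth1 at 2518 ± 312 CPM (SD, n = 2). A higher level than any of these, 26472 ± 4985 CPM (SD, n = 2), was assigned to an unannotated locus on the minus strand of chromosome 17 at 39843013 to 39848827 (mm10), which overlaps the annotated rRNA gene CT010467.1 on the same strand. Protein-coding genes took 88.0% ± 1.61 of endogenous reads, long noncoding genes 0.900% ± 0.0680 and pseudogenes 0.772% ± 0.0600 (SD, n = 2). Over both libraries 17896 annotated genes had at least 1 read, 14354 of them in both, and 11200 had 10 or more.

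Levels in the 2 libraries ran together across 11200 annotated genes, with Pearson's r of 0.945 and Spearman's rho of 0.950 on log2(CPM + 1), where genes are not independent replicates. The difference still exceeded counting error, with a chi-square of 21120 on 13072 degrees of freedom, and the common biological coefficient of variation was 0.0977. Choroid plexus genes were among those that differed. Ttr, the transthyretin gene of the choroid plexus (ENSMUSG00000061808.4, chromosome 18), had 35.7 CPM from 23 reads in replicate 1 and 1125 CPM from 1214 reads in replicate 2, 31.5-fold higher in replicate 2 (adjusted p = 3.3e-204, exact binomial test). Enpp2, which encodes autotaxin (ENSMUSG00000022425.16, chromosome 15), was 3.88-fold higher in replicate 2 (169 and 657 CPM, adjusted p = 1.9e-49, exact binomial test). Clic6 had 1 read in replicate 1 and 26 in replicate 2, a ratio of 15.5 with a counting interval of 2.55 to 635. In the other direction Ptgds, the prostaglandin D synthase gene of meninges and oligodendrocytes, was 2.27-fold higher in replicate 1 (441 and 195 CPM, adjusted p = 3.6e-16), and the nuclear noncoding RNA Malat1 was 2.71-fold higher in replicate 1 on 50 and 31 reads (adjusted p = 0.00232, exact binomial tests).

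**Figure D1:**
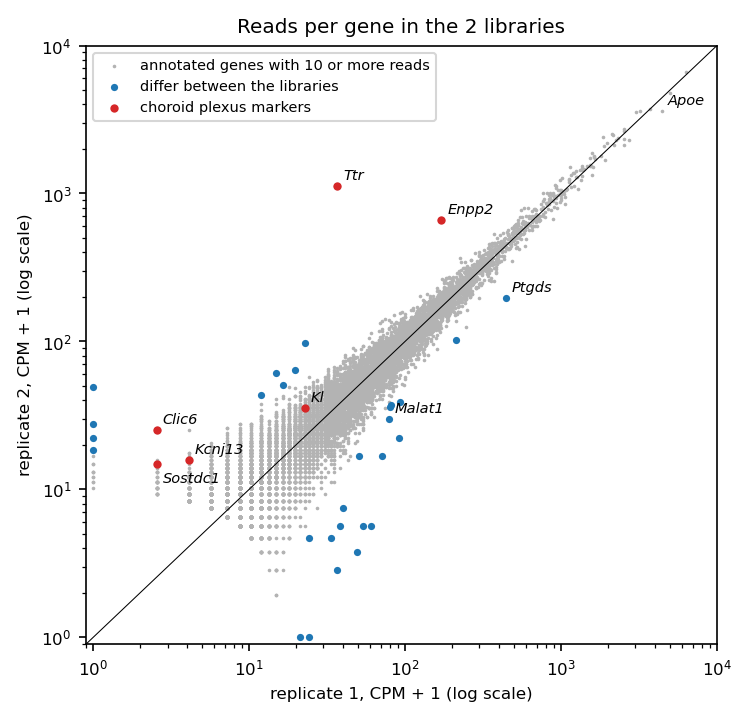
CPM + 1 of each annotated gene with 10 or more reads in replicate 1 (horizontal) and replicate 2 (vertical), on log axes, with called genes in blue and choroid plexus markers in red. Ttr stands at 35.7 CPM in replicate 1 and 1125 CPM in replicate 2.

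In all, 53 of 13073 genes and loci passed the exact binomial test at a ratio of 2 or more, 23 higher in replicate 2 and 30 higher in replicate 1, and 31 of them were annotated genes (12 and 19). At any ratio 113 had an adjusted p under 0.05, against 1067 at an unadjusted p under 0.05. The interneuron gene Calb2, named after its values were seen, was 3.22-fold (log2 1.69) and 1500015O10Rik 3.92-fold higher in replicate 2. With known transcripts only Calb2 was not called, at a log2 ratio of 1.70, and 1500015O10Rik had too few reads for the test. Most other named calls ended when reads were pooled with those of overlapping genes and loci on the same strand, a test chosen after the values were seen. A call was taken to end where the pooled reads differed by less than 2-fold or at an unadjusted p of 0.05 or more. The pseudogene Gm10774 was 4.31-fold higher in replicate 2 and Usp50, which overlaps it, 11.4-fold higher in replicate 1, and together they had 43 and 70 reads (log2 ratio -0.04). Zfp428 was 3.38-fold higher in replicate 2 (pooled log2 ratio 0.14). The pseudogene Gm29216 was 12.7-fold (pooled -0.50), 1 annotated entry of Hgs 8.81-fold (pooled 0.05) and the pseudogene Gm6969 8.05-fold (pooled -0.12) higher in replicate 1. Bcl2l2 had 23 and 2 reads, a ratio of 19.3 in favour of replicate 1 with an interval of 4.77 to 169, and 23 and 25 reads when pooled with Gm20521. Col20a1 had 31 and 3 reads, a ratio of 17.3 with an interval of 5.41 to 88.6, and 86 and 165 reads when pooled, so that both calls ended. Of the called features 20 had reads in only 1 library, among them Vil1 with 29 reads in replicate 2 and none in replicate 1, at least 5.76-fold higher, and the antisense gene Gm43126 with 52 and none, at least 10.3-fold higher, and both calls ended when pooled. Of the 53, 39 overlap another gene or locus on the same strand and 34 ended when pooled. An intergenic locus on chromosome 17 with 0 and 18 reads, not among the 34, reversed its direction when pooled (log2 ratio -1.11). For 29 of the 53 the partners leaned the other way at an unadjusted p under 0.05, and a call can also end by dilution with a larger partner. The partner of the called Hgs entry is another annotated entry of the same name, with 89 and 187 reads. Together they had 110 and 191 reads, so the ratio of 8.81 is of 1 entry and not of Hgs as a whole. The division of reads between overlapping genes, or between pseudogenes and their parents, is uncertain. The split by direction depended on scaling. TMM factors raised all log2 ratios of replicate 2 over replicate 1 by 0.11 and called 37 higher in replicate 2 and 24 in replicate 1, and DESeq2 size factors raised them by 0.14 and called 48 and 24.

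Markers of neurons, glia and vessels were detected, and sums over lists of different sizes do not give shares of cell types. The 14 general neuronal markers summed to 10761 ± 609 CPM (SD, n = 2), with Snap25 at 1718 ± 119, Nefl at 1677 ± 52.6 and Syp at 1242 ± 121 CPM. Glutamatergic markers summed to 3913 ± 105 CPM, with Slc17a7, the vesicular glutamate transporter, at 1450 ± 127 and Nrgn at 1336 ± 40.5 CPM (SD, n = 2). Dentate granule cell markers summed to 477 ± 17.3 CPM, with Calb1 at 193 ± 22.1 and C1ql2 at 170 ± 8.22 (SD, n = 2). GABAergic markers summed to 1122 ± 101 CPM, with Cck at 513 ± 106 and Gad1 at 348 ± 23.4 (SD, n = 2). Astrocyte markers summed to 5193 ± 92.1 CPM, led by Aldoc at 1381 ± 82.9 and the glutamate transporter Slc1a3 at 841 ± 6.92 (SD, n = 2). Oligodendrocyte markers summed to 5019 ± 8.79 CPM, led by the myelin gene Mbp at 2430 ± 131 (SD, n = 2). Microglial markers summed to 1702 ± 99.4 CPM, of which the widely expressed Cd81 gave 1026 ± 136 and Csf1r 127 ± 12.1 (SD, n = 2). Endothelial and pericyte markers summed to 399 ± 38.4 CPM with Cldn5 at 100.3 ± 12.1, and oligodendrocyte precursor markers to 275 ± 4.89 CPM with Olig1 at 82.5 ± 13.1 (SD, n = 2). Of neighbouring tissues, thalamic markers were low, at 59.5 ± 4.99 CPM and led by Prkcd at 33.1 ± 9.49. Ependymal markers were low too, at 10.7 ± 8.50 CPM with 4 of 6 detected. Choroid plexus markers were not, at 233 CPM in replicate 1 and 1883 CPM in replicate 2, and meningeal markers summed to 407 ± 183 CPM (SD, n = 2). By the exact binomial test over all genes and when adjusted over the list alone, 1 and 3 neuronal, 0 and 1 glutamatergic, 1 and 1 GABAergic, 1 and 2 oligodendrocyte and 1 and 1 microglial markers differed. Among these were Slc17a7, Cck and Cd81. No dentate granule, precursor, endothelial, ependymal or thalamic marker passed in either way, against 0, 1, 1, 0 and 0 at an unadjusted p under 0.05. Only 1 of 6 ependymal and 2 of 6 thalamic markers had the 10 or more reads needed for the test, so it says little on those tissues.

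**Figure D2:**
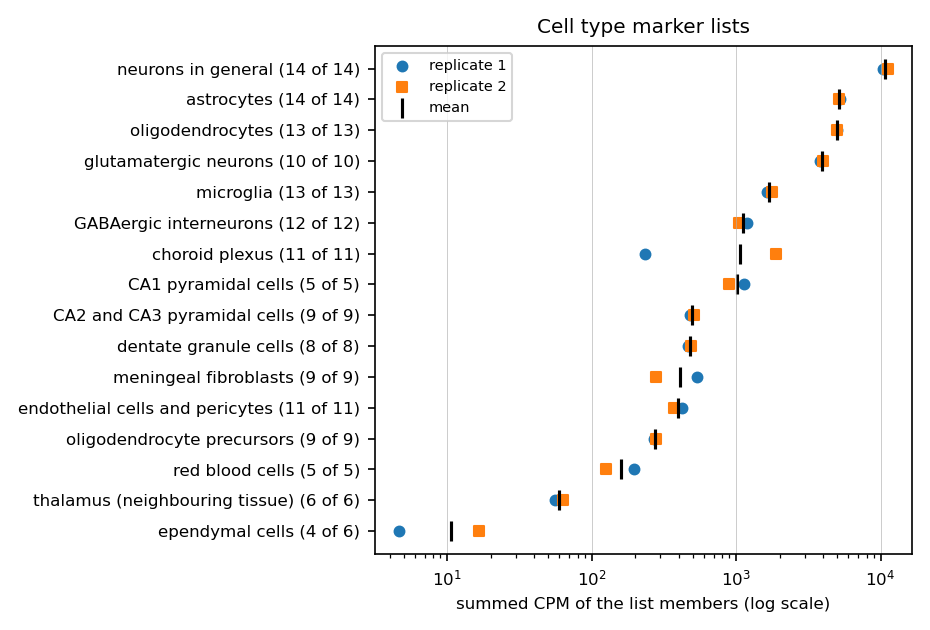
Summed CPM of each list of cell type markers in replicate 1 and replicate 2, on a log axis. General neuronal markers sum to 10330 and 11192 CPM, and choroid plexus markers to 233 and 1883 CPM.

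Against random lists of matched expression, 7 of the fixed lists had a median ratio outside the central 95%. Percentiles were not adjusted over the lists, so some lists would lie outside without any difference between the libraries. Members of random lists were drawn independently, whereas markers of a cell type may vary together. Choroid plexus markers had a median log2 ratio of replicate 2 over replicate 1 of 2.30, at percentile 100, with 3 members past the test over all genes and 5 when adjusted over the list alone. CA1 pyramidal markers had a median of -0.46 (percentile 0.02), with Wfs1 at -0.46 (adjusted p = 0.0068, exact binomial test) and 3 members past the test when adjusted over the list alone. With known transcripts only the CA1 median was -0.23 (percentile 5.65), inside the central 95%. CA2 and CA3 markers had a median of 0.52 (percentile 99.91), with none past the test over all genes and 2 when adjusted over the list alone, Amigo2 at 0.80 and Pcp4 at -0.42. Red blood cell genes stood at -0.67 (percentile 0.68), with Hba-a1 at 90.9 ± 34.2 CPM and Hbb-bs at 33.0 ± 6.07 (SD, n = 2), and at percentile 5.71 with no minimum of reads, which ends the call. Of these 1 passed when adjusted over the list alone and 0 over all genes, and near-identical hemoglobin copies leave the split between genes uncertain. Immediate early genes, induced by neuronal activity, had a median of -0.31 (percentile 0.56). None passed the exact binomial test in either way (2 at an unadjusted p under 0.05), and the group was led by Arc at 195 ± 34.4 CPM and Junb at 174 ± 26.2. Abundant long noncoding RNAs had a median of -0.32 (percentile 0.65), with Malat1 the member past the test and Meg3 at 319 ± 16.6 CPM. That list fell inside the central 95% with no minimum of reads (percentile 13.36), with known transcripts only (5.62) and without single-exon models outside annotated transcripts (13.88). The astrocyte median of -0.12 (percentile 1.64; 0 past the exact binomial test in either way, 4 at an unadjusted p under 0.05) was 0.01 with DESeq2 size factors, which shift every gene alike and leave the percentile at 1.64. With known transcripts only the GABAergic (-0.35, percentile 1.0), endothelial (-0.44, percentile 1.34) and meningeal (-1.04, percentile 0.145) medians also lay outside, as did the splicing list without single-exon models outside annotated transcripts (-0.07, percentile 0.665). The meningeal list summed to 407 ± 183 CPM, of which Ptgds, its 1 member past the test, gave 318 ± 175 and Dcn 39.1 ± 4.12 CPM (SD, n = 2).

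Synaptic genes were among the abundant groups. The 21 synaptic vesicle genes summed to 11377 ± 757 CPM, with Nsf at 1429 ± 33.2 and Vamp2 at 1318 ± 254 (SD, n = 2). In that list 2 members passed the test over all genes and 6 when adjusted over the list alone, and Vamp2 was 0.40 higher in replicate 2 on the log2 scale (adjusted p = 3.7e-07, exact binomial test). Heat shock genes summed to 6870 ± 694 CPM with 3 past the test over all genes and 5 when adjusted over the list alone. Hspa5, an endoplasmic reticulum chaperone gene, was 0.47 higher in replicate 2 (adjusted p = 5.7e-05, exact binomial test). Ionotropic glutamate receptors summed to 2892 ± 84.1 CPM, led by Gria1 at 807 ± 25.4, Grin1 at 734 ± 45.2 and Gria2 at 698 ± 4.26, and GABA-A subunits to 1220 ± 42.0 CPM, with Gabra5 at 276 ± 34.2 (SD, n = 2). None passed the exact binomial test in either list, adjusted over all genes or adjusted over the list alone, against 1 glutamate receptor gene and 0 GABA-A genes at an unadjusted p under 0.05. Genes linked to Alzheimer disease and tau summed to 8313 ± 549 CPM, with App at 1398 ± 44.3, Ptk2b at 1079 ± 15.6 and Clu at 449 ± 31.0 (SD, n = 2), and 1 of them, Apoe, passed the exact binomial test, both over all genes and when adjusted over the list alone (log2 ratio -0.29, adjusted p = 3.1e-12). Of the reactive and ageing glia list 13 of 16 were detected, at 2167 ± 87.7 CPM in sum with Ctsb at 733 ± 71.2, Gfap at 630 ± 43.8 and the complement gene C4b at 104 ± 7.48, while Lcn2, Cst7 and Clec7a had no reads. Interferon and antigen presentation genes were low, at 182 ± 11.9 CPM with 12 of 14 detected and H2-D1 at 46.9 ± 7.02. Imprinted genes summed to 2273 ± 44.9 CPM, led by Snrpn at 1045 ± 1.24, and mitochondrially encoded mRNAs to 928 ± 81.6 CPM with mt-Co1 at 323 ± 17.9 (SD, n = 2). The 97 genes with known alternative splicing summed to 44227 ± 165 CPM, and all were detected, with 4 past the test over all genes and 5 when adjusted over the list alone. Among the interferon, imprinted and mitochondrial genes none passed in either way, against 1, 2 and 1 at an unadjusted p under 0.05. In these lists 6 of 14, 12 of 20 and 11 of 13 members had the 10 or more reads needed for the test. Among the glial genes none passed over all genes and 1, Ctsd, when adjusted over the list alone.

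Known models took 61.8% ± 2.59 of endogenous reads and ISM models 10.4% ± 0.407 (SD, n = 2). NIC models took 7.47% ± 0.0838 and NNC models 4.29% ± 0.0900, genomic models 5.98% ± 0.729, antisense models 8.92% ± 1.39 and intergenic models 1.08% ± 0.0657 (SD, n = 2). Replicate 2 had more reads in known models, 63.7% (95% Clopper-Pearson interval 63.6 to 63.8) against 60.0% (59.9 to 60.1). It had fewer in antisense models, 7.94% (7.89 to 7.99) against 9.90% (9.82 to 9.97). The NIC share differed by 0.119 percentage points (adjusted p = 0.0042, Fisher's exact test). ISM models mostly lacked the 5' end of the annotated chain, with 71.8% and 71.9% of their reads in suffixes. Of antisense reads 98.3% were single-exon in each library, and the largest antisense loci after that on chromosome 17, chosen after their values were seen, lay opposite Cplx2 (2251 ± 112 CPM), Slc1a2 (1950 ± 88.6) and Shank1 (1498 ± 220 CPM, SD, n = 2). The strand of single-exon reads is uncertain, and so are these levels. Priming within transcripts or genomic DNA was not checked, so what the single-exon antisense, intergenic and genomic reads derive from is open. ERCC reads were 0.951% and 0.978% of all reads, 43 ERCC transcripts were detected in each library, and 0.858% (0.643 to 1.12) and 0.966% (0.789 to 1.17) of their reads had a class other than known. Of those 53 and 103 reads, 52 and 103 were antisense, with 50 and 78 on a single transcript, so they bear little on the other classes.

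**Figure D3:**
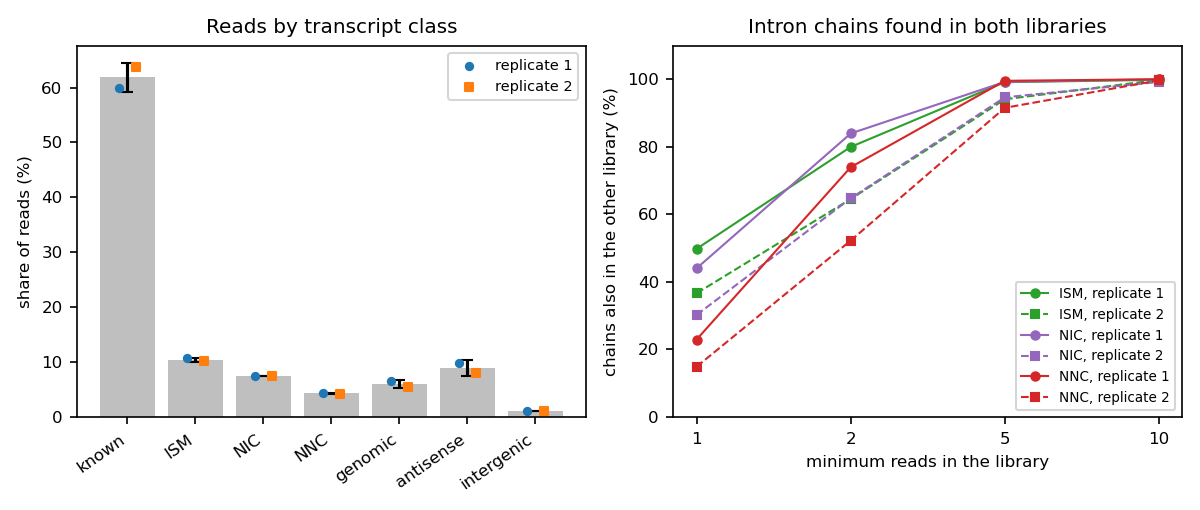
Share of endogenous reads in each transcript class in replicate 1 and replicate 2, in percent (left), and the share of NIC and NNC chains also found in the other library by minimum reads (right). Known models hold 60.0% and 63.7% of reads, and antisense models 9.90% and 7.94%.

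Unannotated intron chains recurred between the libraries more often where they held more reads. Of NIC chains with at least 1 read, 44.0% of replicate 1 and 30.2% of replicate 2 were also in the other library, and with 5 or more reads 99.2% and 94.7%. The NNC shares were 22.9% and 14.9% with at least 1 read, and 99.5% and 91.6% with 5 or more. The chain with most reads was an NNC model of Nrgn, the calmodulin-binding neurogranin gene, on chromosome 9 at 37544492 to 37552904, with 3 exons and 1 intron that is not annotated, at 1251 ± 33.1 CPM (SD, n = 2). NIC chains of Cpne6 (681 ± 147 CPM), Oaz1 (631 ± 62.2), Apbb1 (518 ± 59.4), Aplp2 (333 ± 13.2) and Camta2 (331 ± 62.0) followed, with an NNC chain of Pitpna at 378 ± 22.4 CPM and NIC chains of Oaz2 at 323 ± 21.5, Ctbp1 at 302 ± 38.7 and Sept7 at 299 ± 17.3 CPM (SD, n = 2). Each of the Oaz1 and Oaz2 chains has 4 introns, all 4 shared with 1 annotated transcript, so they show no intron that this transcript lacks. The Cpne6 and Camta2 chains were ISM models in replicate 2, as 7.08% of the 25691 shared chains had another class in the other library. The largest intergenic locus lay on chromosome 4 at 133096030 to 133101553, 6884 nt from Gm26615, at 594 ± 42.0 CPM, followed by a locus on chromosome 15 at 103619060 to 103619240 at 404 ± 39.5 CPM (SD, n = 2).

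At least 2 isoforms were in use in 657 of 2123 genes, 30.9% (29.0 to 33.0). The leading isoform held a median of 86.9% of a gene's reads, and it was annotated in 1974 genes and unannotated in 149. The leading isoform held 97.0% ± 0.143 of Apoe (SD, n = 2), whereas Ppp3ca, the calcineurin catalytic gene, divided between 2 annotated isoforms that differ by a 30-nt exon, at 60.4% ± 3.62 and 35.4% ± 3.16. The myelin gene Mbp also divided: the leading isoform held 72.4% ± 2.04 and an isoform that differs by a 123-nt exon 13.6% ± 1.55 (SD, n = 2). The M1 form of Pkm held 88.3% ± 0.0798 and the form with the other of a pair of exclusive exons 9.63% ± 0.221, and the isoforms of Snap25 that differ in a pair of 118-nt exons held 90.3% ± 0.939 and 7.33% ± 0.0200 (SD, n = 2). The App isoform without the protease inhibitor exon held 699 of 777 reads in replicate 1 and 1234 of 1372 in replicate 2. The leading isoform was an unannotated NIC model in Tpm3 (77.7% ± 0.261), Aplp2 (67.0% ± 0.176), Apbb1 (64.8% ± 0.275), Atp2b1 (49.0% ± 2.56) and Bin1 (44.6% ± 2.55) (SD, n = 2). The same isoform led in both libraries in 2048 genes. In all 2123 genes, the share of the isoform with the highest mean share was tested, whether or not it led in both libraries. That share differed in 5 by Fisher's exact test (100 at an unadjusted p under 0.05): Cpne6, 4833439L19Rik, Dync1li2, Camta2 and Gpr162, named after their values were seen. The Camta2 model had 185 of 291 reads in replicate 1 and 0 of 218 in replicate 2. When a chain was given 1 class in both libraries, a choice made after the data were seen, only Gpr162 still differed (66.3% of 92 reads and 90.4% of 135, adjusted p = 0.0252, Fisher's exact test). Without replicate 1, where the limits apply to replicate 2 alone, 1325 genes had at least 2 isoforms in use.

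**Figure D4:**
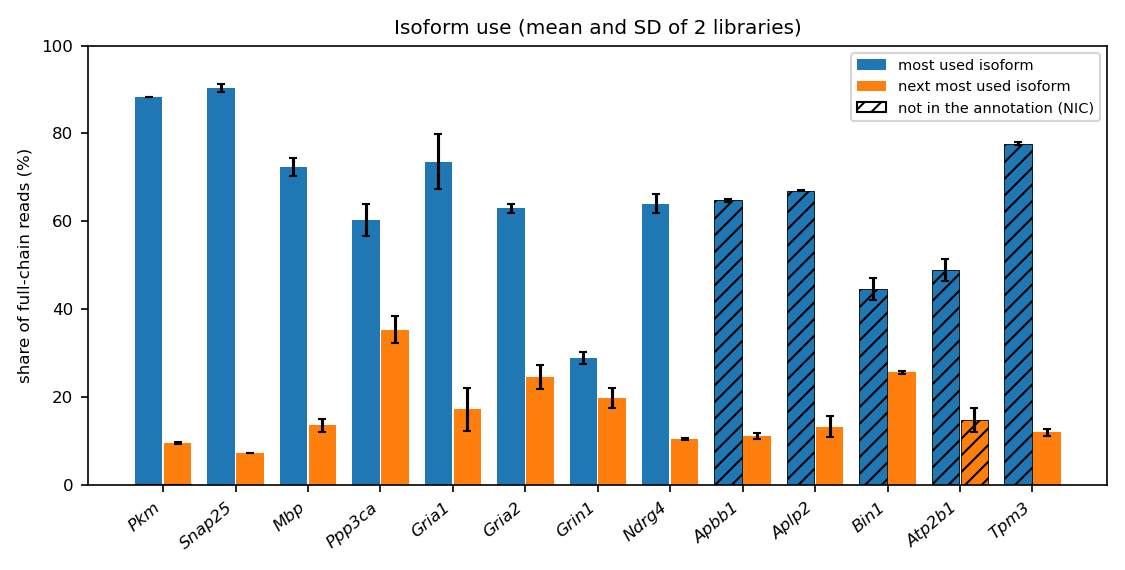
Share of full-chain reads held by the most used and the next most used isoform of genes of the splicing list, in percent (mean and SD of 2 libraries), with unannotated isoforms hatched. The most used isoform holds 88.3% of Pkm and 29.0% of Grin1.

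Of 51244 internal exons measured, 1243 in 853 genes (2.43%) had intermediate inclusion in both libraries, and 44562 were constitutive. The AMPA receptor genes showed their exclusive flip and flop exons. In Gria1 the flop exon (chromosome 11, 57309769 to 57309883) was included in 80.5% ± 6.26 of reads and the flip exon (57310608 to 57310722) in 18.3% ± 6.08 (SD, n = 2). In Gria2 flop stood at 70.9% ± 0.593 and flip at 30.1% ± 0.427, and in Gria3 the order was the reverse, with flip at 69.7% ± 3.37 and flop at 32.1% ± 1.71 (SD, n = 2). In Grin1, the obligatory NMDA receptor subunit, the 111-nt coding exon near the 3' end was included in 48.9% ± 1.22 and the 63-nt exon in 13.8% ± 1.37. The 30-nt exon of Ppp3ca (chromosome 3, 136932011 to 136932040) was included in 63.3% ± 3.20, the 45-nt exon of Camk2b in 88.1% ± 1.13 and the 42-nt exon of Ndrg2 in 28.9% ± 0.397 (SD, n = 2). The 2 N-terminal 87-nt exons of Mapt, the tau gene, stood at 26.6% ± 6.43 and 12.5% ± 1.21 and the 15-nt exon of Itsn1 at 41.1% ± 1.12 (SD, n = 2). Outside the list, the 57-nt exon of Rtn3 stood at 24.0% ± 0.0461 and the 186-nt exon of Pja2 at 29.4% ± 0.661. Intermediate exons, coding or not, were more often a multiple of 3 nt long than constitutive ones, 62.8% (60.1 to 65.5) against 38.6% (38.1 to 39.0) (odds ratio 2.69, p = 8.1e-65, Fisher's exact test over exons, which are not independent replicates). Of the 898 intermediate exons that are coding, 648 (72.2%) were multiples of 3. Microexons were intermediate more often than longer exons, 63 of 323 (19.5%) against 2.32% (odds ratio 10.2, p = 8.7e-38, Fisher's exact test), and 56 of the 63 were multiples of 3. Inclusion differed between the libraries in 0 exons after adjustment by Fisher's exact test, against 34 at an unadjusted p under 0.05. Without replicate 1, where the limits apply to replicate 2 alone, 2250 exons were intermediate.

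**Figure D5:**
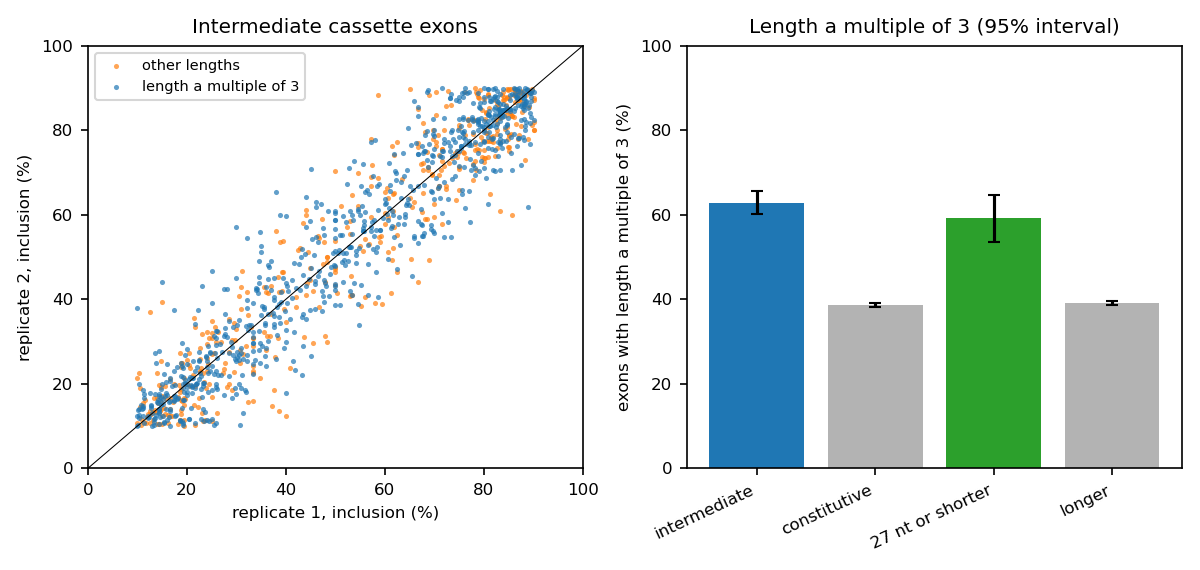
Inclusion in percent of the 1243 intermediate exons in replicate 1 (horizontal) and replicate 2 (vertical), by length (left), and the share of exons with a length that is a multiple of 3 in each set, with 95% Clopper-Pearson intervals (right). That share is 62.8% for intermediate and 38.6% for constitutive exons, and 59.1% for microexons and 39.2% for longer ones.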

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

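The tests on the spike-in strand rate, the ribosomal locus, the choroid plexus markers, the Ttr interval and the pooled overlapping genes were chosen only after the results were seen, and the test on spliced antisense introns before. No biological explanation was tested for any pattern here, since the labels give 1 group.

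A signal appeared in data outside the main measurement: ERCC transcripts are added in 1 orientation, and 52 reads in replicate 1 and 103 in replicate 2 were nevertheless called antisense to them, where none were expected. They came from 3 and 4 of the 43 detected transcripts, with 50 and 78 reads on a single transcript, so the signal was not general. This bears on endogenous antisense reads, 9.90% and 7.94% of the libraries. Turned reads at the overall spike-in share were argued against as the whole source, as the endogenous share was 8.22-fold the spike-in share or more in each library. The ribosomal locus on chromosome 17 held 29.6% of antisense reads on average, so most antisense reads lay elsewhere, and 7.11% and 5.78% of reads were antisense without it. Among introns of spliced antisense reads, 46.2% on average were annotated on the other strand (43.4%, 40.8 to 46.1, of 1370, and 48.9%, 46.7 to 51.2, of 1927). Turned reads of the sense gene may therefore give part of the spliced antisense reads, namely those with introns annotated on the other strand. Whether such introns make up over 0.5 of the introns of spliced antisense reads was not decided, because the interval of replicate 2 includes 0.5.

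Of the choroid plexus list Ttr, Enpp2 and Clic6 were called. The 9 markers other than Ttr and Enpp2 had 18 reads in replicate 1 and 109 in replicate 2 (28.0 and 101 CPM), a ratio of 3.61 (p = 1.1e-08, exact binomial test), and without Clic6 the 8 others had 17 and 83, a ratio of 2.91 (p = 1.1e-05, exact binomial test). The counting interval of the Ttr CPM ratio began at 20.9, which argues against the gap in depth, since depth alone leaves CPM alike. Choroid plexus tissue carried into replicate 2 is a candidate explanation that stays open, as does another difference between the samples or preparations, which was not tested. The most abundant members were Ttr (35.7 and 1125 CPM) and Enpp2 (169 and 657 CPM), of which Enpp2 is also known from oligodendrocytes, and all 11 markers of the list were detected. Kl had 14 and 37 reads, a ratio of 1.58 with a counting interval of 0.832 to 3.16, and was not called.

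Of the 53 called genes and loci, 20 had reads in 1 library only. When their reads were pooled with those of overlapping genes and loci on the same strand, the difference ended for 18 of the 20, 90% (68.3 to 98.8), and for 15 of the 20 the partners leaned the other way at an unadjusted p under 0.05. The same reads assigned to different overlapping genes in the 2 libraries may explain these calls. Among all 53, 34 ended and 19 did not by this rule, 7 called higher in replicate 2 and 12 in replicate 1, and 14 of the 19 had no such partner. Among the 7 was an intergenic locus on chromosome 17 (5816057 to 5816200) with 0 and 18 reads. Pooled with Gm10231, also among the 19, it had 45 and 35 reads (log2 ratio -1.11), so its direction reversed. For 29 of the 53 the partners leaned the other way at an unadjusted p under 0.05, and other calls can end by dilution with a larger partner or at the minimum ratio.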

How the results depend on the processing

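DESeq2 scaling of gene lists, reconciled classes, merged chains, omission of single-exon models, annotated exons and the ERCC results were chosen only after the data were seen. Of 74 alternatives for the main results 49 stayed within tolerance and 25 did not, where counts had to stay within 1.5 times, the coefficient of variation within 0.001, shares within 1 SD between replicates and odds ratios past their test. This does not say which genes were shared. Of the alternatives for single genes, lists and shares 210 did so, 4 moved, 6 fell short of the threshold and 4 newly passed it. A further 1, the astrocyte median with DESeq2 size factors, was counted as changing sign. Some other list medians also changed sign but were counted among the 210. With TMM the glutamatergic median went from -0.0132 to 0.0986 and the GABAergic median from -0.0429 to 0.0689. With known transcripts only the oligodendrocyte precursor median went from 0.065 to -0.062. No paired analysis was possible because the samples form 1 group. The SIRV alternatives and the known-transcript test of 1500015O10Rik, which had too few reads, could not be given.

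The 53 genes and loci that differed became 26 with 50 or more reads, 113 with no minimum ratio, 92 without genomic models and 17 with known transcripts. They numbered 61 with TMM and 72 with DESeq2 factors, 47 shared with the 53 in each case, and 52 without single-exon genomic, antisense and intergenic models, of which only 21 were shared (16 higher in replicate 2, 36 in replicate 1). The coefficient of variation was 0.118 with no minimum, 0.0931 with 50 or more reads and 0.0924 with known transcripts. The astrocyte median was 0.0148 with DESeq2 size factors, a shift common to all genes that left its percentile at 1.64. The known share was 74.2% over multi-exon models, and chains in both libraries made up 28.5%, or 70.8% with 2 or more reads and 96.6% with 5 or more. Genes with at least 2 isoforms in use numbered 1541 with 20 or more reads, 267 with 100 or more, 319 at 20% and 383 with known transcripts. Genes with a differing leading share numbered 10 with 20 or more reads, 3 with 100 or more, 3 with ISM models counted, 0 with known transcripts and 1 with reconciled classes. Intermediate exons numbered 1942 with 10 or more reads, 505 with 50 or more, 678 at 20% to 80% inclusion and 364 with known transcripts. Fewer reads, genes or exons enter under the stricter minimums, and the cause was not tested otherwise.

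With each replicate left out in turn, isoform genes ranged from 770 to 1325 (1325 without replicate 1), intermediate exons from 1532 to 2250 (2250 without replicate 1), genes with 10 or more reads from 9152 to 11001, the known share from 60.0% to 63.7% and the frame odds ratio from 2.08 to 2.34. Read minimums and limits then apply to the remaining library alone, so counts of isoform genes and exons can rise without any difference between the libraries. With counting error alone simulated, the gene test recovered 8 of 50 changes of 2-fold, where the minimum ratio also removes calls. It recovered 37 of 50 at 4-fold, among them 26 of the 26 with 100 or more reads.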

Other observations

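The test of exon pairs was planned before its result was seen, and the genes named for it were chosen after their values were seen. It asked whether pairs of intermediate exons in 1 molecule were chosen independently. Of 557 pairs in 236 genes, 244 passed Fisher's exact test in both libraries with 1 direction, 43.8% (39.6 to 48.0), where at most 5% would pass under independence. In 204 the exons occurred together, in 40 apart, and in 0 in opposite directions in the 2 libraries. With at least 1 exon between them, 104 of 373 pairs passed (27.9%), 90 together and 14 apart. An exon between can itself be a cassette exon that goes with the pair, so these pairs need not show coupling at a distance. In Ttc3 a 124-nt exon lies between the 46-nt and 64-nt exons of a passing pair. The 124-nt exon occurred with the 64-nt exon in 177 and 310 molecules, and 57 and 105 held neither. Pairs within a gene are not independent of each other, and 127 genes had a passing pair.

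In Rtn3 the 2124-nt exon was seen with the 57-nt exon in nearly every case: 69 and 139 molecules held both, 34 and 86 the 57-nt exon alone, and 1 and 0 the 2124-nt exon alone. In Grin1 the 63-nt and the 111-nt exons tended to occur apart: 8 and 27 molecules held both, 175 and 266 the 111-nt exon alone, 42 and 65 the 63-nt exon alone, and 150 and 249 neither. In Gria1 flip and flop were both in 0 of 455 and 2 of 738. In Bin1 the 129-nt and 24-nt exons occurred together, in 100 and 233 molecules with both and 29 and 46 with neither. Mixtures of cell types with different isoforms may give such pairs without any coupling within a cell (43.8% passing is open to that), and neither this nor a difference between the parental alleles was tested.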
